A study of Mus musculus with 17 samples.

How the data were processed

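RNA from the hypothalamus of 17 male C57Bl/6 mice aged 9 weeks was measured on Affymetrix mouse expression arrays, 1 array per hypothalamus. Per the labels, 6 mice were controls injected with vehicle, 6 received a single intraperitoneal dose of streptozotocin (200 µg/g body weight) and 5 were ob/ob mice. The labels give no injection for the ob/ob mice beyond the shared protocol text. RNA was isolated with a column kit, and 10 µg per hypothalamus was turned into biotin-labelled cRNA with an oligo(dT) primer, per the label protocols. The deposited values are in the unit intensity: the authors gave 1 MAS5 signal per probe set and array (MAS5, per the submitters' processing notes), whose version, scaling target and detection calls they did not state. From the values themselves, all 22690 signals of each array were positive (0.1 to 48576.7), on a linear scale, with a 2% trimmed mean of 1500.4 on every array, so the arrays had been scaled to a common mean. Correlations between arrays ran from 0.9543 to 0.9724, and 0 pairs of arrays were identical. Groups and replicate numbers came from the array titles, which state no batch, date or pairing.

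The 64 control probe sets were left out. Signals were taken as log2, and probe sets under the 40th percentile of mean log2 signal over all 17 arrays (a geometric mean of 435) were left out before the test, which left 13576. Of the 22626 remaining probe sets before that filter, 20380 had 1 gene symbol, 691 several and 1555 none. Of those with 1 symbol 20351 matched the mouse gene table by Entrez identifier, with 0 symbols updated. A gene was represented by its brightest probe set, with probe sets of the cross-hybridizing _x_at kind used only where there was no other, for 7954 genes tested. The files name no genome build for the probe sets, so no coordinates are given.

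One model of 3 group means was fitted with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, with statmod 1.5.0. The 3 contrasts were STZ against control, ob/ob against control and ob/ob against STZ, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. The last contrast is also the test of whether the effects of the models differ, since both were set against the same controls. Before the data were examined, 29 gene lists were fixed (synthesis, transport and regulation of cholesterol, fatty acid synthesis, feeding and neurosecretory peptides, signalling, stress, fuel, clock and cell type or region markers), and 8 genes are in more than 1 list. Of these 25 were tested with limma's camera (preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over lists and contrasts. Lists with fewer than 4 measured members had no set test, and a list of X and Y genes served only to check the labels. The mean level of each list per array was compared with an exact two-sided permutation test over all 924 splits of 6 against 6 or 462 of 5 against 6 arrays. Counts of list members are given over all probe sets tested and adjusted over the list alone. The lists of cholesterol biosynthesis, SREBP regulation and cholesterol uptake follow the topic the study drew from these samples.

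Genes were named by a rule fixed before the data were examined. For each comparison with control these were the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, filled up by the smallest p and then given as not passing. For ob/ob against STZ the rule took 5 and 5. Another 14 genes of cholesterol and feeding control were to be named whatever their values, and the 3 members with the smallest p were named from each list that passed. Of the 14, 4 had no probe set with 1 symbol and are not analysed here, and 2, Insr and Lepr, were under the signal filter. List members that passed when adjusted over the list alone, and called genes whose passing probe set was not the representative, are named besides and were chosen after their values were seen. Called probe sets with several symbols or none are counted but not named.

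The whole procedure was tested on simulated data of the same size and of the same spread per probe set. Their noise was independent between probe sets, without correlated genes or a structure of the arrays, so the rates need not carry over to the real data. A 1.41-fold change was recovered for 78, 87 and 73% of changed probe sets in the 3 contrasts and a 2-fold change for 100, 98 and 98%, with 4.3, 1.6 and 3.9% of calls false. The precision of every value is limited by the number of arrays, and the median standard error of a log2 fold change was 0.081 for STZ and 0.085 for ob/ob against control. Median signal and the ratios of 3 prime to 5 prime control probe sets of Gapdh and Actb did not differ between the groups (exact permutation, adjusted p at least 0.626). Principal components 1 and 2 held 19 and 9.13% of the variance; component 2 differed between ob/ob and control by an exact permutation p of 0.0173 (0.26 after adjustment over 15 checks).

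The alternatives tried were quantile normalization, median centring, a pseudocount at the 10th percentile of signals (47.6), no filter, a filter at the 60th percentile, the replicate number as a block, fits of only the 2 groups compared, array weights, a robust variance prior, 1 probe set per gene, the mean of all probe sets of a gene, and leaving out each array in turn. Another 3 were chosen after seeing the data: the Actb ratio as a covariate, leaving out the array of each group that correlated least with its group, and the mean level of neighbouring-region markers as a covariate. That level was the per-array mean of 22 measured genes of the striatum, cortex and hippocampus, and thalamus lists. For each contrast 100 splits of the arrays into groups of the same sizes, the real one included, were fitted in the same way. No array was left out of the reported values.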

Results

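Gene expression in the hypothalamus was measured on Affymetrix arrays in male C57Bl/6 mice aged 9 weeks, with 1 array for each of 17 hypothalami. There were 6 control mice given vehicle, 6 mice made diabetic with streptozotocin (STZ), a toxin of the insulin-producing beta cells, and 5 ob/ob mice, which lack leptin and become obese and insulin resistant. The values were deposited MAS5 signals for 22690 probe sets, between 0.1 and 48576.7 on a linear scale. The median signal of an array averaged 669 in the controls, 685 in STZ and 683 in ob/ob, and the 2% trimmed mean was 1500.4 on every array. Of the probe sets, 13576 were bright enough to be tested, 12526 of them with 1 gene symbol. Differences below are log2 fold changes with their standard error (SE) from limma, and signals are geometric means of the group. The limma and exact permutation p-values measure the spread between these samples. Those of camera set the genes of a list against other genes at a preset correlation of 0.01 between genes. Where estimated, that correlation ran up to 0.42, for the immediate early genes. The series title states that the study concerned diabetes and insulin in the control of brain cholesterol metabolism, so its cholesterol and SREBP (sterol regulatory element binding protein) gene lists are not independent evidence of a direction.

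The comparison of STZ with control mice asked what loss of insulin did in the hypothalamus. B2m and H2-K1, of MHC class I, and Igtp, an interferon-induced GTPase, rose in STZ mice, while Pomc, the precursor of the appetite-suppressing peptide alpha-MSH, fell. B2m, the class I light chain, rose by 0.38 ± 0.059 (n = 6 and 6), from a signal of 6560 to 8540 (adjusted p = 0.0137). H2-K1, a heavy chain, rose by 0.53 ± 0.089 on its representative probe set and by 0.76 ± 0.12 on another (adjusted p = 0.0219 and 0.0137). All H2-K1 probe sets tested were of the cross-hybridizing _x_at kind, so other class I heavy chains may add to this signal. Igtp rose 2.03-fold, from 433 to 879 (1.02 ± 0.18, adjusted p = 0.0412), and Pomc fell to 0.635 of its control signal, from 1680 to 1070 (-0.65 ± 0.12, adjusted p = 0.0384).

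In all, 7 probe sets passed an adjusted p of 0.05 in STZ against control, 6 higher and 1 lower, for 5 named genes and 1 probe set with several symbols. Slc2a1, the glucose transporter of the blood-brain barrier, passed on a probe set other than its brightest, at 0.31 ± 0.051 (adjusted p = 0.0199). Its other probe sets gave 0.29 and 0.30 without passing (adjusted p = 0.134 and 0.145). The other B2m probe set gave 0.21 (adjusted p = 0.374), and the other H2-K1 probe sets gave 0.40 and 0.57 (adjusted p = 0.613 and 0.0507). Each of these 5 genes differed in 6 of 6 STZ arrays, with no overlap between the groups on the probe sets that passed. At an unadjusted p under 0.05 there were 1119 probe sets, 525 higher and 594 lower, where chance would give 679. The next genes by p did not pass: Gbp7 and Iigp1, both interferon-induced GTPases, at 0.59 and 0.83, and Myrf, a transcription factor of myelinating cells, at 0.41 (adjusted p = 0.0507, 0.0939 and 0.0792). On the lower side Cxcl12, a chemokine, stood at -0.47 (-0.295 with the mean of its probe sets), Chordc1, a co-chaperone of Hsp90, at -0.35, and Aqp4, the astrocyte water channel, at -0.26 (adjusted p = 0.0973, 0.103 and 0.134). Smarca4, a chromatin remodelling ATPase, stood at -0.19 (-0.0416 with that mean), Acp6, a lysophosphatidic acid phosphatase, at -0.45, and Acss1, a mitochondrial acetyl-CoA synthetase, at -0.26 (adjusted p between 0.134 and 0.146).

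**Figure D1:**
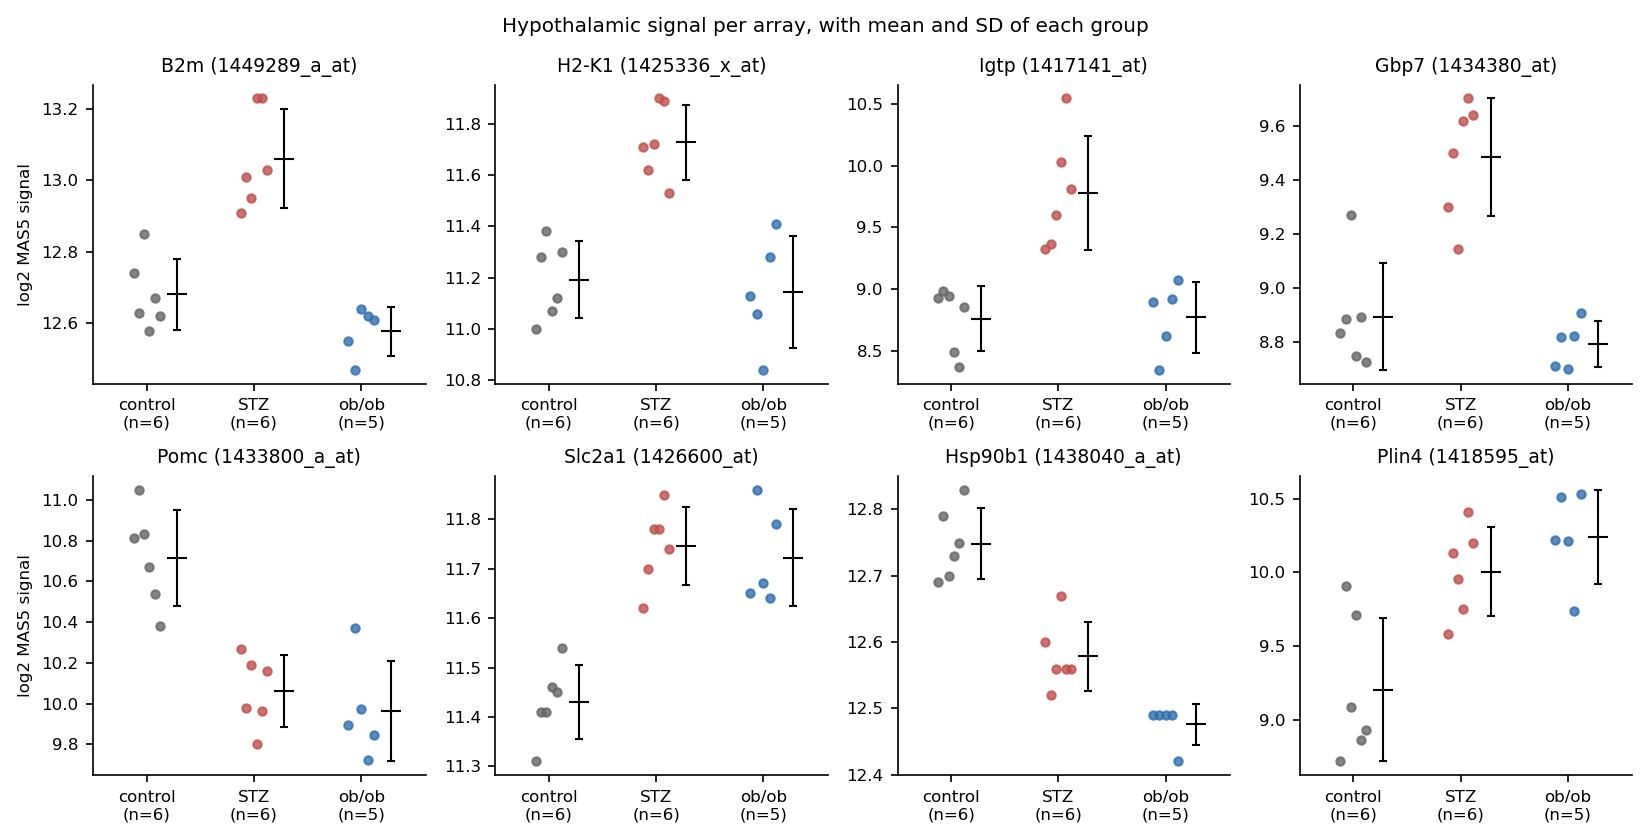
Log2 MAS5 signal of 8 genes on each array (y axis), by group (x axis: control n = 6, STZ n = 6, ob/ob n = 5); points are arrays, and the black marks are the mean with the SD of the group. The 6 STZ arrays of B2m, H2-K1 and Igtp lie above all control and ob/ob arrays, and Pomc lies lower in both STZ and ob/ob than in any control array.

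Genes of lipid synthesis were lower as groups in STZ mice by camera. By the exact permutation test of per-array list means, adjusted over the lists, no list passed in STZ. That test gave an adjusted p of 0.227 for cholesterol biosynthesis (0.0455 before adjustment) and 0.162 for fatty acid synthesis, the smallest. In the cholesterol biosynthesis list 15 of 17 measured enzymes had a negative value, with a median of -0.07 (limma's camera, adjusted p = 0.000132, and adjusted p = 0.0921 with an estimated correlation). Adjusted over the list alone, 5 fell (Idi1, Fdps, Fdft1, Sqle and Msmo1), and over all genes tested 0 passed (limma; 5 had an unadjusted p under 0.05). Without control 6 or without STZ 4 the count over the list alone was 0, as it was with the neighbouring-region marker level as a covariate, where the median was -0.034. This list follows the study's own topic and its count is not independent evidence. Idi1 and Fdps, enzymes of the isoprenoid steps, stood at -0.25 ± 0.068 and -0.20 ± 0.061, and Sqle, the squalene epoxidase, at -0.20 ± 0.061. Hmgcs1, the enzyme of HMG-CoA synthesis, stood at -0.08 ± 0.045 (adjusted p = 0.653). The SREBP regulators did not differ as a list (5 measured, median -0.012, mean 0.0022, adjusted p = 0.896; limma, 0 passed in either adjustment and 0 at an unadjusted p under 0.05). Srebf1 and Srebf2, the transcription factors themselves, stood at -0.012 ± 0.093 and -0.055 ± 0.054, and Scap, their escort protein, at 0.039 ± 0.093. This list too was drawn from the study's topic. In cholesterol uptake, transport and turnover 1 of 15 measured genes fell when adjusted over the list alone, Lcat, which esterifies cholesterol, at -0.31 ± 0.08. The list itself did not differ (median -0.0056, adjusted p = 0.53; limma, 0 passed over all genes and 2 had an unadjusted p under 0.05), and as a list of the study's topic it is not independent evidence. Fatty acid synthesis genes were lower in 12 of 13 measured (median -0.098, adjusted p = 1.63e-05), and this held with an estimated correlation (adjusted p = 0.0488). Adjusted over the list alone, 3 fell (5 without control 2): the elongases Elovl5 and Elovl6 at -0.18 and -0.19, and Acss2, which makes acetyl-CoA from acetate, at -0.25. Over all genes 0 of them passed (limma; 4 had an unadjusted p under 0.05). The mean level of neighbouring brain region markers (22 genes of striatum, cortex and thalamus) differed from the controls by 0.13 in these STZ arrays (exact permutation p = 0.0844).

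Chaperone genes were lower and glucocorticoid-responsive genes higher in STZ mice by camera. The exact permutation test, adjusted over the lists, called none of them. Its adjusted p was 0.227 for heat shock, 0.325 for the unfolded protein response, 0.227 for glucocorticoid-responsive and 0.271 for immediate early genes. Of 11 measured heat shock genes 6 fell when adjusted over the list alone, among them Cryab, a small heat shock protein, at -0.35 ± 0.084, Hsph1, a chaperone of the Hsp110 family, at -0.21 ± 0.058, and Hspe1, a mitochondrial chaperonin, at -0.28 ± 0.086. The count was 3 without control 3, control 5, STZ 2 or STZ 4, and 2 with the neighbouring-region marker level as a covariate. The list had a median of -0.11 (camera, adjusted p = 0.000167, and adjusted p = 0.0712 with an estimated correlation), and over all genes 0 passed (limma; 6 had an unadjusted p under 0.05). The unfolded protein response list, of endoplasmic reticulum chaperones, had a median of -0.07 over 16 genes (adjusted p = 0.0106, and adjusted p = 0.243 with an estimated correlation), and it was -0.044 with that covariate, where it did not pass (adjusted p = 0.128). Its Calr, a calcium-binding chaperone, fell when adjusted over the list alone (-0.15 ± 0.043), but 0 did with the covariate or without control 2, STZ 2, STZ 4, STZ 5 or STZ 6. In the same list Manf and Hsp90b1 stood at -0.16 and -0.11, the latter at -0.0671 without control 1. Of 15 glucocorticoid-responsive genes 14 had a positive value (median 0.12, adjusted p = 1.25e-05, and adjusted p = 0.145 with an estimated correlation). Adjusted over the list alone 3 rose (5 without control 2, control 6 or STZ 5): Tsc22d3, the glucocorticoid-induced leucine zipper, at 0.24 ± 0.051, Plin4, a lipid droplet protein, at 0.80 ± 0.19, and Sult1a1, a sulfotransferase, at 0.48 ± 0.14. Over all genes 0 of these passed (limma; 5 had an unadjusted p under 0.05). All 9 immediate early genes had a positive value (median 0.29, adjusted p = 0.00216, and adjusted p = 0.313 with an estimated correlation), with Dusp1, a phosphatase, at 0.45, Nr4a1, an orphan receptor, at 0.34 and Fos at 0.46. None of these 9 passed adjusted over the list alone or over all genes (limma; 1 had an unadjusted p under 0.05). Striatum markers, from a neighbouring region, had a median of 0.12 (adjusted p = 0.043, and adjusted p = 0.466 with an estimated correlation), with Ppp1r1b at 0.24, Rasgrp2 at 0.13 and Pde10a at 0.38. Without control 3 Ppp1r1b was 0.132 and Pde10a 0.202, without STZ 4 they were 0.118 and 0.222, and Rasgrp2 was 0.0847 without STZ 1 and 0.211 without STZ 3. None of the 8 passed in either adjustment (limma; 0 had an unadjusted p under 0.05), and the list did not pass without control 3, control 6, STZ 1, STZ 2 or STZ 4 (adjusted p from 0.0926 to 0.406), with a filter at the 60th percentile or in a fit of only these 2 groups (adjusted p = 0.0519 and 0.0558).

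Among 9 feeding peptides and receptors Npy, which stimulates appetite, rose and Pomc and Cartpt, which suppress it, fell when adjusted over the list alone. Npy stood at 0.34 ± 0.077 and Cartpt at -0.35 ± 0.078, while only Pomc passed over all genes, and the list itself did not pass (median -0.06, adjusted p = 0.0659). In fasting and fuel switching 2 of 14 genes rose when adjusted over the list alone, Slc2a1 and Angptl4, an inhibitor of lipoprotein lipase, at 0.46 ± 0.12, with a list median of 0.01 (adjusted p = 0.651). Insulin and leptin signalling, with 17 genes, had a median of 0.04 and a mean of -0.02 (adjusted p = 0.853), with 0 passing (limma; 2 had an unadjusted p under 0.05). Cell type markers did not differ as lists: medians were 0.0039 for oligodendrocytes (mean -0.016), 0.043 for astrocytes, 0.015 for microglia (mean -0.0053), -0.032 for neurons, -0.027 for endothelium and pericytes, and 0.03 for tanycytes and ependyma. The thalamus and cortex markers stood at medians of 0.058 and 0.12, and Ramp3 of the thalamus list rose when adjusted over the list alone (0.64 ± 0.18). Medians for the remaining lists were -0.016 for oxidative phosphorylation, -0.00079 for glycolysis, 0.032 for synapse genes, 0.086 for circadian clock genes and 0.03 for neurosecretory peptides. Apart from the feeding list, the smallest adjusted p among the lists that did not pass was 0.113, for oxidative phosphorylation.

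The count was 0 by limma without STZ 4 or STZ 5, 1 without control 5, 4 without control 1 or control 4, 12 without STZ 3 and 18 without STZ 1, and B2m missed the threshold without 3 of the 12 arrays, H2-K1 without 5, Igtp without 8 and Pomc without 9 (adjusted p from 0.0521 to 0.154). With the level of neighbouring-region markers as a covariate, chosen after seeing the data, 0 passed by limma (980 at an unadjusted p under 0.05): the 7 probe sets kept 92.6 to 115% of their size while the standard error grew 1.18-fold (median).

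The comparison of ob/ob with control mice asked what leptin deficiency with obesity and insulin resistance did in the same tissue. Chaperones and Pomc fell in ob/ob mice, and the lipid droplet gene Plin4 rose. Plin4 rose 2.05-fold, from 589 to 1210 (1.04 ± 0.20, n = 5 and 6, adjusted p = 0.0449), and Pomc fell to 0.594 of its control signal, from 1680 to 997 (-0.75 ± 0.12, adjusted p = 0.0121). Hsp90b1, the Hsp90 of the endoplasmic reticulum, fell by 0.27 ± 0.037 on a probe set other than its brightest (adjusted p = 0.00645). Its brightest stood at -0.201 without passing, and its groups overlapped (adjusted p = 0.239). The co-chaperone Chordc1 fell by 0.48 ± 0.078 (adjusted p = 0.0121). Myrf rose by 0.46 ± 0.084 and Slc2a1, on the same probe set as in STZ, by 0.29 ± 0.054 (both adjusted p = 0.0305). The other Slc2a1 probe sets gave 0.337 and 0.301 without passing (adjusted p = 0.0558 and 0.0687).

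In all, 17 probe sets passed, 6 higher and 11 lower, for 14 named genes and 3 probe sets without a single symbol, and 1611 had an unadjusted p under 0.05 (780 higher and 831 lower, 679 expected by chance). Gabra2, a GABA-A receptor subunit, fell by 0.51 ± 0.085 (adjusted p = 0.0159). Ptch1, the receptor of Hedgehog ligands, fell by 0.33 ± 0.052 (adjusted p = 0.0121), with its other probe set at -0.015. Cacybp, a calcyclin-binding protein, fell by 0.20 ± 0.036 (adjusted p = 0.0305). Hr, a corepressor of nuclear receptors, rose by 0.60 ± 0.12 (adjusted p = 0.0449), with its other probe set at 0.028. Another 4 genes passed on a probe set that was not the representative of the gene: Grb10, an adaptor that dampens insulin receptor signalling, at -0.52 ± 0.08, Ndn, an imprinted neuronal gene, at -0.42 ± 0.071, Brix1, a ribosome assembly factor, at -0.50 ± 0.091, and Hsph1 at -0.38 ± 0.071. The other probe sets of Grb10 (-0.082 and -0.042), Brix1 (-0.034) and Ndn (adjusted p from 0.0558 to 0.288) did not pass. Each of these genes differed in 5 of 5 ob/ob arrays, with no overlap between the groups on the probe sets that passed, except for Plin4, whose groups overlapped. Next by p, not passing, were Tsc22d3, Klf13, a transcription factor, Hrh3, a histamine autoreceptor, Sult1a1 and Tef, a clock output factor, at 0.26, 0.27, 0.33, 0.70 and 0.18. On the lower side were Manf, Ttc30a1, an intraflagellar transport gene, and Aqp4 at -0.31, -0.50 and -0.29 (adjusted p from 0.0558 to 0.0687).

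Glucocorticoid-responsive genes were higher as a group in ob/ob mice, 14 of 15 with a positive value and a median of 0.26 (camera, adjusted p = 1.43e-08, and adjusted p = 0.0712 with an estimated correlation; exact permutation p = 0.00649). Adjusted over the list alone 8 rose and 1, the glucocorticoid receptor Nr3c1, fell, against 1 over all genes, Plin4, and with the neighbouring-region marker level as a covariate 5 did over the list alone. Fkbp5, a receptor co-chaperone, stood at 0.43 ± 0.097, Sgk1, a kinase, at 1.21 ± 0.36 and Tsc22d3 at 0.26 ± 0.053. In these arrays the markers of neighbouring regions were also higher, by 0.25 (11.23 against 10.98, exact permutation p = 0.00649).

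Both chaperone lists were lower in ob/ob mice. Of 11 heat shock genes 7 fell when adjusted over the list alone, with a median of -0.20 (adjusted p = 4.22e-06), and this held with an estimated correlation (adjusted p = 0.0488). The count over the list alone was 4 without control 6 or ob/ob 3, 1 without ob/ob 5, and 1 with the neighbouring-region marker level as a covariate, where the median was -0.129. The brightest Hsph1 probe set stood at -0.29 ± 0.061, Hspd1, a mitochondrial chaperonin, at -0.13 ± 0.044 and Cryab at -0.26 ± 0.088, and over all genes 0 passed on the brightest probe set (limma; 7 had an unadjusted p under 0.05). Of 16 unfolded protein response genes 8 fell when adjusted over the list alone (median -0.14, adjusted p = 4.86e-06, and adjusted p = 0.0712 with an estimated correlation). These included Manf, Pdia3, a disulfide isomerase, at -0.30 ± 0.075, and Calr at -0.17 ± 0.045, with 0 passing over all genes on the brightest probe set (limma; 9 had an unadjusted p under 0.05). With the covariate 0 of its members passed over the list alone. The neighbouring-region markers were 0.25 higher in the same ob/ob arrays, while both chaperone lists were lower.

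Feeding peptides were lower in ob/ob mice, a call that held with an estimated correlation (median -0.13 over 9 genes, adjusted p = 0.000695 and, with an estimated correlation, adjusted p = 0.0488). The median ran from -0.0882 to -0.257 (without ob/ob 1) on leaving out 1 array. Adjusted over the list alone 4 fell, Pomc, Hcrt, the precursor of the wake-promoting orexins, Gal, the neuropeptide galanin, and Cartpt, and Npy rose, while Pomc alone passed over all genes. Hcrt stood at -0.50 ± 0.11, Gal at -0.29 ± 0.072, Cartpt at -0.29 ± 0.082 and Npy at 0.27 ± 0.081. The neighbouring-region markers were 0.25 higher in these arrays, and with their level as a covariate Hcrt stood at -0.192, Gal at -0.137 (adjusted p = 0.833 and 0.832) and 1 member passed over the list alone. Cholesterol biosynthesis genes did not differ as a list between ob/ob and control mice (17 measured, median 0.02, adjusted p = 0.896; limma, 0 passed in either adjustment and 2 had an unadjusted p under 0.05: 1 higher and 1 lower), in a list of the study's topic. Hmgcs1 stood at -0.0081 ± 0.048 and Sqle at -0.057 ± 0.064. The SREBP list had a median of -0.016 and a mean of 0.052 (adjusted p = 0.651; limma, 0 passed in either adjustment and 1 had an unadjusted p under 0.05), with Srebf1 at -0.054, Srebf2 at -0.016 and Scap at 0.24 ± 0.097. In cholesterol uptake, transport and turnover Lcat fell when adjusted over the list alone (-0.29 ± 0.084), and the list did not differ (median -0.035, mean 0.0071, adjusted p = 0.86). Both lists follow the study's topic and are not independent evidence. Fatty acid synthesis genes had a median of -0.061 (adjusted p = 0.00353, and adjusted p = 0.118 with an estimated correlation). There Elovl5 fell when adjusted over the list alone (-0.17 ± 0.049; 3 members did without control 2, and 0 with the covariate or without control 4, control 6, ob/ob 1, ob/ob 3, ob/ob 4 or ob/ob 5), and Acss2 and Me1, the malic enzyme, stood at -0.19 and -0.15. With the mean of its probe sets Me1 was -0.0265, and with the neighbouring-region covariate Acss2 was -0.113.

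**Figure D2:**
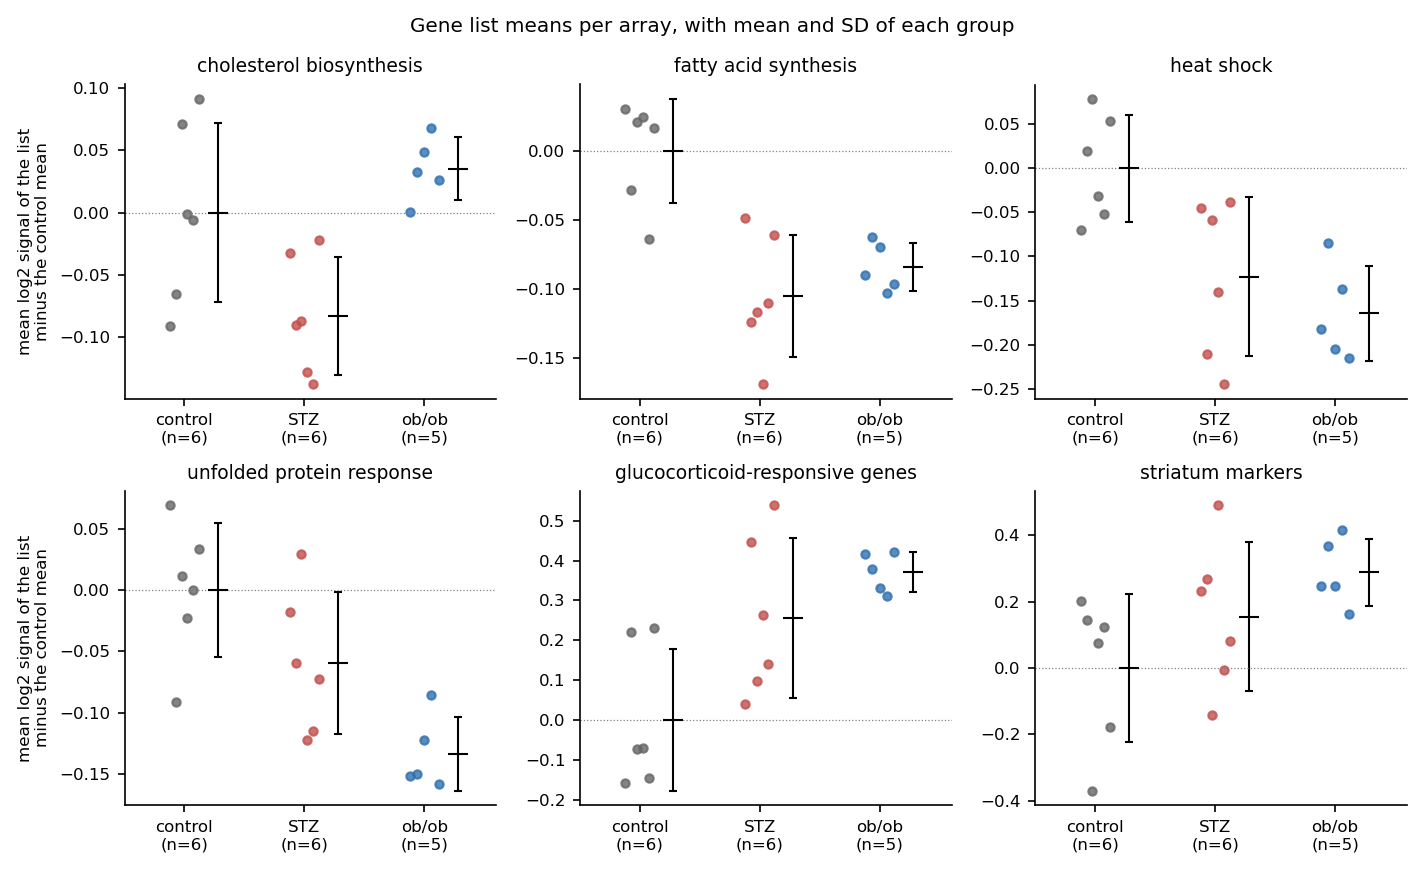
Mean log2 signal of 6 gene lists on each array, minus the mean of the control arrays (y axis), by group (x axis: control n = 6, STZ n = 6, ob/ob n = 5); points are arrays, and the black marks are the mean with the SD of the group. The mean of the cholesterol biosynthesis list was -0.083 in STZ and 0.035 in ob/ob relative to control, and that of the striatum markers 0.15 and 0.29.

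Clock and early response genes were higher as lists in ob/ob mice by camera. By the exact permutation test, adjusted over the lists, clock genes and striatum markers passed (adjusted p = 0.0232 and 0.0406). Early genes, microglia markers and cortex and hippocampus markers did not (adjusted p = 0.253, 0.153 and 0.0661). Circadian clock genes had a median of 0.15 over 16 genes (adjusted p = 0.0144, and adjusted p = 0.0712 with an estimated correlation), with Tef rising when adjusted over the list alone, Rora, a nuclear receptor, at 0.28 and Per2, a clock repressor, at 0.29. The clock list did not pass with the neighbouring-region marker level as a covariate (0.0706, adjusted p = 0.574) or with a filter at the 60th percentile (0.128, adjusted p = 0.0667), and those markers were 0.25 higher in ob/ob. Its member Rora is also part of that covariate. Immediate early genes had a median of 0.21 (adjusted p = 0.0144, and adjusted p = 0.432 with an estimated correlation), with Dusp1 rising when adjusted over the list alone (0.51 ± 0.15), and Egr3 and Klf4, transcription factors, at 0.51 and 0.45. Klf4 stood at 0.23 without ob/ob 1, and the median at 0.135 without control 5, 0.126 without ob/ob 1 and 0.388 without ob/ob 5. That list did not pass without control 5, ob/ob 1 or ob/ob 2 (adjusted p from 0.0728 to 0.133) or at the 60th percentile (adjusted p = 0.0868). In it 0 members passed over the list alone without control 1, control 2, control 5, ob/ob 1 or ob/ob 2. Microglia markers had a median of -0.07 (adjusted p = 0.0188, and adjusted p = 0.335 with an estimated correlation). In that list Cx3cr1, the fractalkine receptor, fell when adjusted over the list alone (-0.49 ± 0.12), and Ly86 and Tyrobp stood at -0.39 and -0.17 (Tyrobp at -0.103 without ob/ob 1). Over the list alone 0 members passed without ob/ob 5 and 2 without control 2 or ob/ob 4. The list did not pass without control 6 or ob/ob 1 (adjusted p = 0.0702 and 0.224). Nor did it pass at the 60th percentile (adjusted p = 0.056), with the Actb ratio or the neighbouring-region marker level as a covariate (adjusted p = 0.0523 and 0.0559, the latter at -0.0388), or without the least correlated array of each group (adjusted p = 0.187). Striatum markers had a median of 0.26 (adjusted p = 0.000638, and adjusted p = 0.206 with an estimated correlation), with Ppp1r1b rising when adjusted over the list alone (0.48 ± 0.15; 0 members did without control 3, control 6 or any 1 of the ob/ob arrays) and Foxp1 and Rgs9 at 0.24 and 0.29. Cortex and hippocampus markers had a median of 0.24 (adjusted p = 0.0229, and adjusted p = 0.206 with an estimated correlation), with Nrgn at 0.30, Itpka at 0.41 and Egr3, which is also in the early response list. Itpka was 0.263 without control 6, and with the covariate, of which this list is part, Itpka was 0.042, Nrgn 0.07 and Egr3 0.271. The list did not pass without control 3, ob/ob 2 or ob/ob 4 (adjusted p from 0.0501 to 0.0921) or at the 60th percentile (0.147, adjusted p = 0.269). The other cell type lists did not pass camera, with medians of 0.015 for oligodendrocytes, 0.04 for astrocytes, -0.061 for neurons, -0.0017 for endothelium and pericytes (mean -0.036) and 0.12 for tanycytes and ependyma (adjusted p = 0.592). The per-array mean of the tanycyte list was higher by 0.12 (exact permutation p = 0.00649, 0.0232 after adjustment over the lists). Thalamus markers stood at 0.19, insulin and leptin signalling at -0.0052, fasting and fuel switching at 0.012, glycolysis at -0.0077, oxidative phosphorylation at -0.022, synapse genes at 0.03 and neurosecretory peptides at -0.038. None of these lists passed (smallest adjusted p = 0.1, for the neurons).

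Pomc, Chordc1 and Ptch1 passed without any single array, while Gabra2 missed the threshold without 2 of the 11 arrays, Myrf without 6, Plin4 and Cacybp without 8 and Hr without 9 (adjusted p from 0.0512 to 0.118), Pomc and Gabra2 missed it in a fit of only these 2 groups (adjusted p = 0.052 and 0.0543), and the count ran from 8 (without control 1 or control 3) through 9 (without control 5, control 6, ob/ob 2 or ob/ob 5) and 11 (ob/ob 4) to 38 (without control 2) and 43 (without control 4). With the neighbouring-region markers as a covariate, chosen after seeing the data, 0 passed by limma (905 at an unadjusted p under 0.05): the 17 probe sets kept a median of 94.6% of their size (47.4 to 112%) while the standard error grew 1.47-fold (median).

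The direct comparison of ob/ob with STZ mice tested whether the models differed from each other. B2m, H2-K1 and Gbp7 were lower in ob/ob than in STZ mice. B2m stood at 6120 against 8540 (-0.48 ± 0.062, n = 5 and 6, adjusted p = 0.00284) and H2-K1, on its representative probe set, at 2260 against 3390 (-0.59 ± 0.094, adjusted p = 0.0298). Gbp7 stood at 444 against 717 (-0.69 ± 0.12, adjusted p = 0.0308). These 3 genes made up all 5 probe sets that passed, each lower in 5 of 5 ob/ob arrays with no overlap.

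The remaining passing probe sets were the other probe set of B2m (-0.42, adjusted p = 0.0345) and another of H2-K1 (-0.73, adjusted p = 0.0308). The 2 other H2-K1 probe sets, at -0.371 and -0.37, did not pass and their groups overlapped (both adjusted p = 1). In all 533 probe sets had an unadjusted p under 0.05 (262 higher and 271 lower), fewer than the 679 expected by chance. Igtp and Iigp1 stood at -1.01 ± 0.19 and -0.89 ± 0.18 without passing (adjusted p = 0.0721 and 0.107). On the higher side the genes with the smallest p were Inafm2 at 0.77, Cxcl12 at 0.42, Rpusd1 at 0.24, Mthfd1, a folate enzyme, at 0.25 and Tcn2, the transcobalamin that carries vitamin B12, at 0.40, and none passed (adjusted p from 0.226 to 0.859). Pomc (-0.096), Npy (-0.071) and Cartpt (0.065) did not differ between the models (adjusted p = 1).

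Cholesterol biosynthesis genes were higher as a list in ob/ob than in STZ mice, 16 of 17 with a positive value (median 0.12, camera, adjusted p = 1.7e-06, and adjusted p = 0.055 with an estimated correlation; exact permutation p = 0.00433, 0.108 after adjustment over the lists). Neither over all genes nor adjusted over the list alone did a member pass (limma; 6 had an unadjusted p under 0.05), and the list follows the study's topic, so it is not independent evidence. Idi1 stood at 0.19 ± 0.071, Fdft1, the squalene synthase, at 0.12 ± 0.048, Sqle at 0.14 ± 0.064 and Hmgcs1 at 0.076 ± 0.048. The SREBP list did not differ (median 0.039, adjusted p = 0.42; limma, 0 passed in either adjustment and 0 had an unadjusted p under 0.05), with Srebf1, Srebf2 and Scap at -0.042, 0.039 and 0.20. Cholesterol uptake, transport and turnover had a median of 0.022 and fatty acid synthesis 0.0087 (adjusted p = 0.62 and 0.476).

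Another 7 lists passed camera in this comparison, and 0 of all lists did with an estimated correlation (fry called 1). The exact permutation test called none after adjustment over the lists (smallest adjusted p = 0.108, for cholesterol biosynthesis). Unfolded protein response genes had a median of -0.085 (adjusted p = 0.000946, and adjusted p = 0.145 with an estimated correlation), with Manf, Pdia3 and Creld2, a disulfide isomerase, at -0.16, -0.18 and -0.21. Glucocorticoid-responsive genes had a median of 0.14 (adjusted p = 0.00461, and adjusted p = 0.344 with an estimated correlation), with Fkbp5 at 0.32, Klf9, a transcription factor, at 0.14 and Mt2, a metallothionein, at 0.16. Microglia markers had a median of -0.094 (adjusted p = 0.00461, and adjusted p = 0.231 with an estimated correlation), with Cx3cr1, Ly86 and Ctss, a lysosomal protease, at -0.30, -0.27 and -0.12. Ly86 was -0.164 without ob/ob 1. Feeding peptides had a median of -0.071 (adjusted p = 0.0145, and adjusted p = 0.0902 with an estimated correlation), with Hcrt and Gal falling when adjusted over the list alone (-0.34 ± 0.11 and -0.23 ± 0.072; 0 members did without STZ 1, STZ 3, ob/ob 1 or ob/ob 4) and the receptor Npy5r at -0.16 (-0.103 without ob/ob 5). Striatum markers had a median of 0.16 (adjusted p = 0.0344, and adjusted p = 0.448 with an estimated correlation), with Ppp1r1b at 0.23, Penk, the enkephalin precursor, at 0.21 and Foxp1 at 0.14. Without STZ 4 the first 2 were 0.358 and 0.327, and without ob/ob 4 Foxp1 was 0.0864. Neurosecretory peptides had a median of -0.068 (adjusted p = 0.0493, and adjusted p = 0.148 with an estimated correlation), with Sst, somatostatin, at -0.084, Scg2, a granin, at -0.10 and Oxt, oxytocin, at -0.19. Oxt was -0.0941 without STZ 3 and -0.114 without ob/ob 4. Clock genes had a median of 0.081 (adjusted p = 0.0493, and adjusted p = 0.138 with an estimated correlation), with Tef, Per2 and Rora at 0.083, 0.21 and 0.17. Leaving out 1 array ended the call for neurosecretory peptides in 9 of 11 cases, clock genes in 8, striatum markers in 6, glucocorticoid-responsive genes in 2 (STZ 1 and STZ 3), microglia in 1 (ob/ob 1) and feeding peptides in 1 (ob/ob 4), with adjusted p from 0.0512 to 0.443. The feeding median was -0.0367 without ob/ob 4, -0.113 without STZ 2 and -0.137 without ob/ob 2, and the list did not pass with no signal filter (adjusted p = 0.0566). Quantile normalization ended the calls of neurosecretory peptides (adjusted p = 0.139), clock genes and striatum markers (both adjusted p = 0.0508). The filter at the 60th percentile ended those of clock genes and striatum markers (adjusted p = 0.0954 and 0.0507). Without the least correlated array of each group none of these 7 passed (adjusted p from 0.0527 to 0.442). With the neighbouring-region marker level as a covariate neurosecretory peptides and clock genes did not pass (adjusted p = 0.317 and 0.452). Penk of the former list and Rora of the latter are also part of that level. The other lists did not pass, among them heat shock (median -0.029, adjusted p = 0.103), immediate early genes (-0.0086), cortex markers (0.21, adjusted p = 0.0528), oligodendrocytes (0.0071) and insulin and leptin signalling (median -0.014, mean 0.012). Neighbouring-region markers were 0.11 higher in ob/ob than in STZ arrays (exact permutation p = 0.0519).

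**Figure D3:**
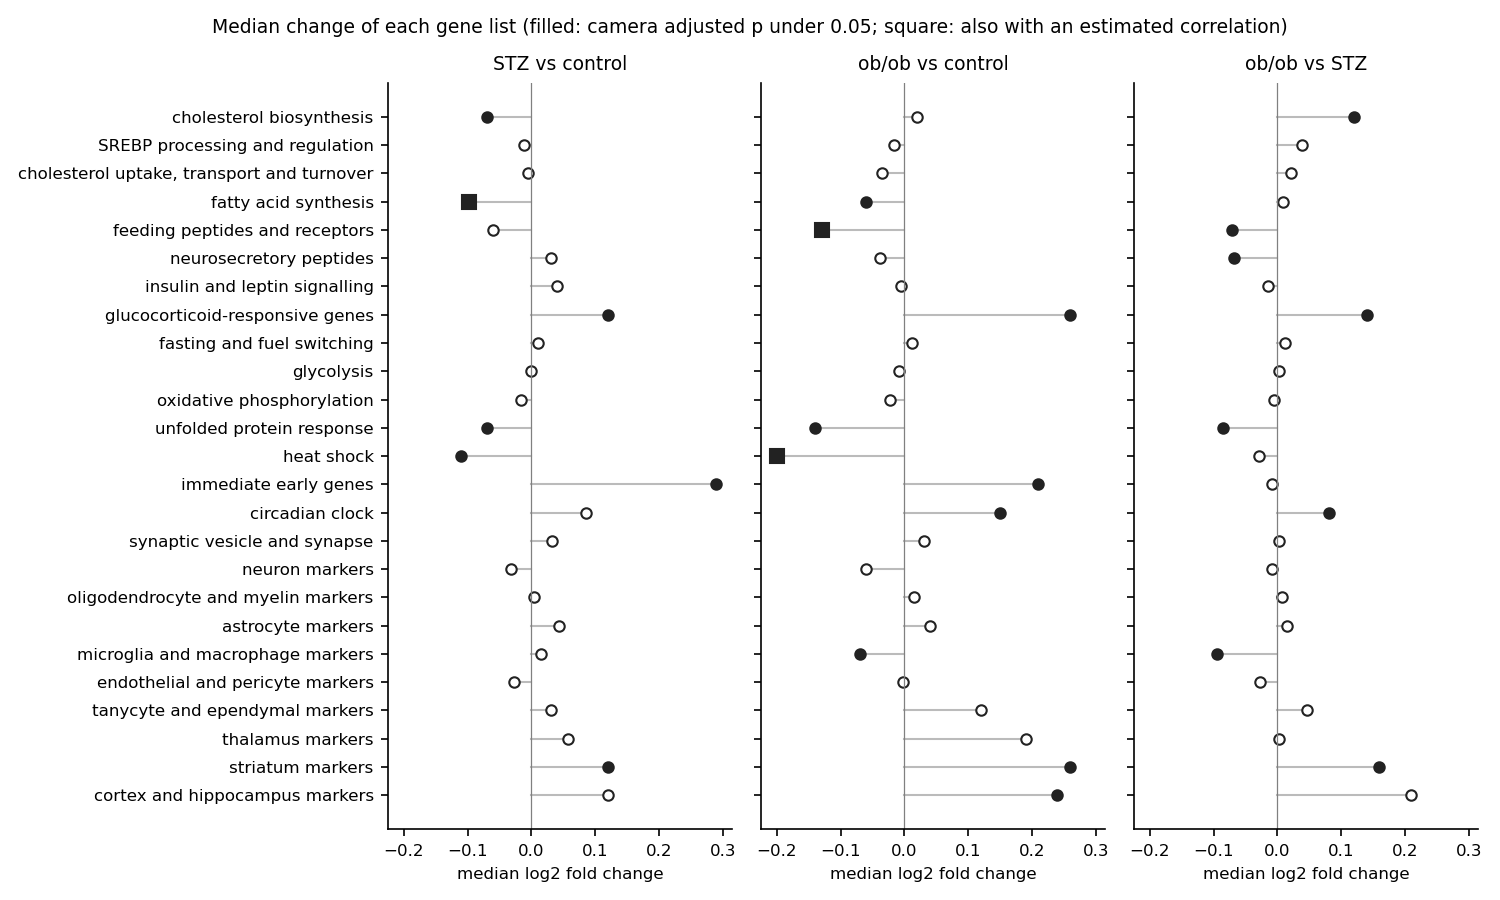
Median log2 fold change of each of 25 gene lists (x axis) in the 3 comparisons (panels); filled marks passed camera at an adjusted p under 0.05, and squares also passed with an estimated correlation. The cholesterol biosynthesis list stood at -0.07 in STZ against control, 0.02 in ob/ob against control and 0.12 in ob/ob against STZ.

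Leaving out STZ 2, STZ 4, STZ 5, ob/ob 2 or ob/ob 3 left 1 passing probe set, ob/ob 4 left 2, STZ 6 left 3 and STZ 1 left 9, and B2m passed without any single array while H2-K1 missed the threshold without 5 of the 11 and Gbp7 without 8 (adjusted p from 0.0513 to 0.155). With the neighbouring-region markers as a covariate, chosen after seeing the data, 1 passed, B2m at -0.45 ± 0.069 (adjusted p = 0.0389).

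The differences of STZ and of ob/ob from the same 6 controls were compared across genes. Pomc was lower in both models and Slc2a1 higher: 2 probe sets passed upward in both and 1 downward, each against the same controls. The upward probe set besides that of Slc2a1, without a single symbol, stood at 0.508 ± 0.077 in STZ and 0.564 ± 0.081 in ob/ob (limma, adjusted p = 0.0137 and 0.00645). Across the 13576 probe sets, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.647. Simulated unchanged groups set against the same controls gave 0.481 on average (0.128 to 0.733), and 10 of 100 simulations were as large. With the controls split 3 and 3 between the comparisons the correlation averaged 0.211 (0.0792 to 0.285 over 20 splits). The covariance was 0.0101 against 0.00611 in the simulations, a difference of 0.00399, and 7 of 100 simulations were as large. The sign was the same for 74.7% of the probe sets, against 66.4% in the simulations.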

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

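The tests of microglia, of single STZ arrays, of neighbouring tissue, of the control arrays and of oligodendrocytes below were chosen only after the result was seen, as were the interferon, leukocyte and cold-inducible gene lists.

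B2m was higher in STZ mice by 0.38, and the 17 measured members of an MHC class I and interferon list, drawn up after the calls were seen, by 0.32 on average. The rise was not confined to the H2 family: the 9 members outside it and not seen before had a median of 0.125 (exact permutation p = 0.013). These 9 cannot decide whether cross-hybridization between H2 genes added to the H2-K1 signal. For H2-K1 it stays open, since all of its tested probe sets were of the cross-hybridizing _x_at kind. The tables argue against more microglia, whose 14 markers differed by -0.00534 ± 0.032. For the whole list they argue against a single aberrant array, since it stayed at 0.278 or more without any 1 STZ array. That list held the genes that had prompted it. The mean of its 9 members not seen before lay above all controls in 4 of 6 STZ arrays. Leukocytes stay open: their 6 measured markers of 24 differed by 0.0613 ± 0.039 (median 0.13, 4 positive), under the bound set beforehand, but their control signals of 489 to 2130 would hide a small share. The drug and the diabetes cannot be separated in these groups, and which cells respond was not tested. For the number of calls in STZ, the real split gave 6 in a fit of those 2 groups, and the highest of the other splits gave 2 (1 of 100 as large). That argues against chance for this count, but only 100 of the possible splits were drawn. The count was also unstable: in the fit of all groups it ran from 0 to 18 on leaving out 1 array.

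Heat shock genes were lower in both models, with medians of -0.105 in STZ and -0.196 in ob/ob on the brightest probe sets (camera; adjusted p = 0.0712 with an estimated correlation in STZ and adjusted p = 0.0488 in ob/ob). Probe set brightness is argued against: 0 percent of 10000 lists of matched signal were as low in STZ (centre -0.0045) and 0 percent in ob/ob (centre -0.014). Neighbouring tissue stays open in ob/ob, where the median was -0.129 with the marker level as a covariate, and so does a difference confined to the shared control arrays, since ob/ob and STZ differed by -0.0418 ± 0.044. A lower brain temperature in both models could also account for it: Cirbp, which cold induces, was higher in STZ by 0.349 ± 0.091 (limma, unadjusted p = 0.0011, adjusted p = 0.229). Its value in ob/ob, 0.43, had been seen when that test was set, and a low level in the controls would raise both. Only 1 of 2 cold-inducible genes had a tested probe set with a single symbol. Probe sets with several symbols or none were not searched for the other, and temperature was not measured.

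Cholesterol biosynthesis genes were lower in STZ (median -0.0697, mean -0.0832; camera, adjusted p = 0.000132, and adjusted p = 0.0921 with an estimated correlation). Brightness is argued against, since 0.32 percent of 10000 matched lists were as low. Neighbouring tissue could account for part of it: with its marker level as a covariate the median was -0.034, having lost more of its size than it kept. Camera still called the list (adjusted p = 0.00629). The covariate cannot decide this, since its level was itself 0.13 higher in STZ than in control (exact permutation p = 0.0844) and can take up a group difference of another cause. Fewer oligodendrocytes stay open, since their markers differed by -0.0156 ± 0.044, a spread too wide to decide. The loss of insulin, which the design names, may also underlie it and was not separated from these.

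For ob/ob against control the real split gave 6 calls in a fit of those 2 groups, and 4 of 100 splits gave as many, the real one included. That share is under the bound set beforehand, but only narrowly. Only 100 of the 462 possible splits were drawn and mixed splits gave more calls than the real one, so chance is not excluded for this count. The highest other split gave 21 calls and the next 14, several times the real count. The first set controls 1, 2 and 3 with ob/ob 1 and 5 apart from the rest, the next controls 4, 5 and 6 with ob/ob 2 and 4. The labels give no batch for these splits, and whether a structure of the samples lies behind them was not tested. For ob/ob against STZ the real split gave 1 call, the highest other 3, and 7 of 100 were as large, so chance cannot be excluded for the count of that comparison.

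The direct comparison of ob/ob with STZ, the test of whether the effects of the models differ, set these results apart: Gbp7 at -0.691, H2-K1 at -0.587 and B2m at -0.482. Among gene lists it set apart cholesterol biosynthesis (median 0.12), feeding peptides (-0.071), neurosecretory peptides (-0.068), glucocorticoid-responsive genes (0.14), the unfolded protein response (-0.085), clock genes (0.081), microglia (-0.094) and striatum markers (0.16), each by camera at its preset correlation. With an estimated correlation 0 of these lists passed (adjusted p = 0.055 for cholesterol biosynthesis to adjusted p = 0.448 for striatum markers), and neurosecretory peptides did not pass without 9 of 11 arrays.

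A sample far from the others of its group was found in 18 of 285 groups of arrays, where chance would give about 14.2. In log2 signal these were Gbp7 in control 3 (9.271, others 8.728 to 8.895), Srebf2 in STZ 6 (11.38, others from 11.6), Manf in ob/ob 3 (11.5, others up to 11.32), Ppp1r1b in ob/ob 4 (11.75, others up to 11.51), Rasgrp2 in STZ 3 (10.29, others from 10.69) and Klf13 in ob/ob 2 (11.42, others up to 11.25). Array ob/ob 5 stood apart for Hrh3 (11.54, others up to 11.3), Cacybp (12.63, others from 12.69), Ttc30a1 (8.589, others from 8.836), Npy5r (9.042, others from 9.305) and Penk (12.78, others from 13.13). Per2 stood apart in control 2 (10.35, others up to 10.01), Itpka in ob/ob 1 (10.61, others up to 10.18), Fdft1 in control 6 (12.18, others up to 12.05) and Oxt in STZ 3 (13.91, others up to 13.41). The mean of the cortex and hippocampus list stood apart in STZ 4 (10.81, others up to 10.5) and that of the neurosecretory list in STZ 3 (12.34, others up to 12.2). The Gapdh ratio of 3 prime to 5 prime was -0.488 in STZ 6, with the others from -0.408.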

How the results depend on the processing

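The Actb ratio, the neighbouring-region level and leaving out the least correlated array of each group were chosen only after the result was seen; the other alternatives were planned. Single calls were sensitive to the arrays and the fit, while the cholesterol, fatty acid, heat shock and glucocorticoid medians against control that passed camera kept their sign and passed camera at the preset correlation under all alternatives run for them, though not all passed with an estimated correlation, with camera adjusted p up to 0.00629 for cholesterol, 0.000939 for fatty acids, 0.00538 for heat shock and 0.00128 for glucocorticoid genes in STZ. Except where stated, the cause was not tested. Signal over background limits what can be seen: probe sets under a geometric mean of 435 were not tested.

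Of the counts (7, 17 and 5 for STZ against control, ob/ob against control and ob/ob against STZ), quantile normalization gave 29 in ob/ob against control, array weights 38 there and 10 in ob/ob against STZ, and the fit of only the groups compared 6 and 1. In ob/ob against STZ no filter gave 1, the 60th percentile 3 and the replicate block 1. The numbers do not pair the arrays, since same-number correlations of the array residuals ran from -0.17 to 0.11. With 1 probe set per gene the counts were 4, 8 and 3, where fewer probe sets were tested. The Actb ratio gave 4 in STZ and the removal of control 2, STZ 3 and ob/ob 1 gave 12. With the neighbouring-region level the counts were 0, 0 and 1 (limma; 980, 905 and 436 at an unadjusted p under 0.05) because standard errors grew 1.18-, 1.47- and 1.12-fold while the sizes kept a median of 106, 94.6 and 94.3%: B2m in STZ went from 0.38 ± 0.059 to 0.42 ± 0.069 (adjusted p = 0.0583) and Pomc in ob/ob from -0.75 ± 0.12 to -0.66 ± 0.18 (adjusted p = 0.482). Some settings, those leaving out 1 array included, added calls. Gbp7 in STZ passed in 8 of 25 settings. In ob/ob against control Manf passed in 9 of 25, and Hsph1 on its brightest probe set in 5 of 25. Other settings ended single calls. With no signal filter Igtp (adjusted p = 0.0741) and Pomc (adjusted p = 0.0569) were lost in STZ, Plin4 (adjusted p = 0.0789) and Hr (adjusted p = 0.0743) in ob/ob, and Gbp7 and H2-K1 in ob/ob against STZ (both adjusted p = 0.0577), where more probe sets were tested. The fit of only the groups compared lost Igtp in STZ (adjusted p = 0.1), Pomc (0.052), Gabra2 (0.0543), Cacybp (0.0677), Myrf (0.0822), Hr (0.0996) and Plin4 (0.102) in ob/ob, and Gbp7 and H2-K1 in ob/ob against STZ (both 0.0726). The replicate block lost Igtp (0.165) and H2-K1 (0.105) in STZ, Plin4 (0.0555), Cacybp (0.0593), Hr (0.0807) and Myrf (0.0869) in ob/ob, and H2-K1 (0.157) and Gbp7 (0.204) in ob/ob against STZ. Array weights lost Igtp in STZ (0.0581), and the robust variance prior Plin4 in ob/ob (0.0541). The Actb ratio lost H2-K1 (0.0584), Igtp and Pomc (both 0.0697) in STZ. Removing the least correlated arrays lost H2-K1, Igtp and Pomc in STZ (each 0.0524), Myrf in ob/ob (0.0576) and H2-K1 in ob/ob against STZ (0.0872). With the mean of all probe sets Ptch1 (-0.17, adjusted p = 0.58) and Hr (0.32, adjusted p = 0.202) lost their calls in ob/ob and H2-K1 (-0.52, adjusted p = 0.0577) in ob/ob against STZ. Camera called 7, 10 and 8 lists, camera with an estimated correlation 1, 2 and 0, and fry 3, 6 and 1. The correlation of effects was 0.211 with the controls split, where the shared controls no longer add to it.

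Signs reversed only for values near 0 or for members of the covariate. In ob/ob against control Hmgcs1 was 0.0133 with quantile normalization, 0.0088 with array weights and 0.0207 with the Actb ratio; the cholesterol median was -0.016 at the 60th percentile; and Srebf2, which is also the SREBP median, was 0.0261 with the mean of probe sets, 0.00159 with the Actb ratio and 0.0256 without the least correlated arrays. For Srebf1, ob/ob vs STZ, the value was 0.00185 with array weights and 0.0346 without the least correlated arrays. With the neighbouring-region level Srebf1 was 0.114, 0.178 and 0.0633 in the 3 contrasts and the SREBP median 0.107 in STZ and 0.178 in ob/ob. The striatum markers that make that level reversed by its construction: Ppp1r1b to -0.0594, -0.0816 and -0.0223, Pde10a to -0.106 in STZ, Foxp1 to -0.0422 and Rgs9 to -0.127 in ob/ob, and Penk to -0.0418 in ob/ob against STZ.

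On leaving out 1 array the STZ count ran from 0 (STZ 4 or STZ 5) to 18 (STZ 1), with 1 without control 5, 4 without control 1 or control 4 and 12 without STZ 3. The ob/ob count ran from 8 (control 1 or control 3) to 43 (control 4), with 9 without control 5, control 6, ob/ob 2 or ob/ob 5, 11 without ob/ob 4 and 38 without control 2. For ob/ob against STZ it ran from 1 (STZ 2, STZ 4, STZ 5, ob/ob 2 or ob/ob 3) to 9 (STZ 1), with 2 without ob/ob 4 and 3 without STZ 6. B2m missed the threshold in STZ without control 5, STZ 4 or STZ 5, H2-K1 also without control 1 or control 4, and Gabra2 in ob/ob without control 3 or ob/ob 5. Igtp and Pomc in STZ, Plin4, Cacybp, Hr and Myrf in ob/ob and Gbp7 in ob/ob against STZ missed it without 8, 9, 8, 8, 9, 6 and 8 arrays. Ranges that crossed 0 were, in STZ, Srebf1 -0.0776 to 0.0366, the SREBP median -0.0389 to 0.0366 and Scap -0.0245 to 0.0934; in ob/ob, Srebf1 -0.103 to 0.0275, Srebf2 -0.037 to 0.00618, the SREBP median -0.0322 to 0.0275, Hmgcs1 -0.0355 to 0.0221 and the cholesterol median -0.000702 to 0.0328; and in ob/ob against STZ, Cartpt -0.00513 to 0.115, Srebf1 -0.0777 to 0.0395 and Srebf2 -0.0041 to 0.0592. Leaving out 1 array also moved these medians over 1.5-fold. In STZ the glucocorticoid median of 0.12 was 0.186 without control 6 and 0.191 without STZ 1 or STZ 5, the early gene median 0.177 without control 5 the striatum median 0.0762 without control 3 and the unfolded protein median of -0.07 was -0.042 without control 1 and -0.0432 without STZ 4. In ob/ob the fatty acid median of -0.061 was -0.0926 without control 6 and -0.0935 without ob/ob 1, and the microglia median -0.0375 without ob/ob 1 and -0.119 without ob/ob 4. In ob/ob against STZ the striatum median was 0.088 without ob/ob 4, and the clock median 0.0373 without ob/ob 1 and 0.054 without ob/ob 5.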

Other observations

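The interferon list, the leukocyte list and the cold-inducible genes were chosen after the data were seen. The MHC class I and interferon list of 37 held the genes that had prompted it, so only its 9 measured members that lay outside the H2 family and had not been seen before serve as a test of the group. In STZ mice all 9 had a positive value (median 0.13), and their mean was higher than control by 0.15 ± 0.052 (exact permutation p = 0.013), above all controls in 4 of 6 arrays. In ob/ob their mean differed from control by -0.023 ± 0.046 (exact permutation p = 0.671) and from STZ by -0.17 ± 0.038 (exact permutation p = 0.00649). Among the 9, Irgm1, an interferon-induced GTPase like Igtp and Iigp1 that had been seen before, stood highest in STZ at 0.47. The mean of the 9 therefore leans on it more than their median does. Stat2, which carries the type I interferon signal, stood at 0.062, and 2 of the 9 had an unadjusted p under 0.05 (limma). Of the whole list 17 members were measured, and in ob/ob against control 1 of them passed when adjusted over the list alone, Oas1a, an antiviral synthetase, lower by 0.746 ± 0.21 (unadjusted p = 0.00234, 0.149 over all genes). The leukocyte list gave -0.0061 ± 0.048 in ob/ob.

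Several genes of lists that did not pass camera still differed from control when adjusted over the list alone. Aqp4, the astrocyte water channel, was lower in both models (-0.26 and -0.29), and Agt, angiotensinogen, was higher in STZ (0.23 ± 0.077). Crym, a thyroid hormone binding protein of tanycytes, was higher in ob/ob (0.75 ± 0.2), as were Prkcd (0.66 ± 0.2) and Rora (0.28 ± 0.098) of the thalamus list. Of the respiratory chain Ndufv1 was higher (0.18 ± 0.048) and Ndufb5 lower (-0.12 ± 0.036) in ob/ob. Carbonic anhydrase 2 (Car2), in the erythroid list of 3 measured genes, was lower in ob/ob (-0.31 ± 0.11). The anterior pituitary list had 2 measured genes, the peptide Gal, which is also a feeding peptide, and the granin Chgb, and its mean was lower by 0.20 in ob/ob (exact permutation p = 0.00216). In STZ that mean also lay lower, at -0.082 against the same controls (exact permutation p = 0.00433). The choroid plexus list had 0 genes bright enough to be tested, and the X and Y list had 4, with 0 called (limma; 0 at an unadjusted p under 0.05).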
